A study of Mus musculus with 4 samples.

How the data were processed

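RNA of cultured mouse spermatogonial stem cells was measured on 4 two-colour Agilent 44K mouse gene expression arrays. Per the labels, channel 1 (Cy3, green) of every array held cells kept without FGF2 and with the FGF receptor inhibitor SU5402 for 12 h, and channel 2 (Cy5, red) held cells in normal culture. The design text gives 4 control and 4 treated biological replicates. Each array therefore carried 1 treated and 1 control sample, and the replicate number of the labels names the array. Dyes were not swapped on any array, so a gene-specific dye effect cannot be separated from the treatment by the design. The file headers place all 4 arrays on 1 slide and in 1 scan, so slide and scan add no batch among these arrays.

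The spot values are intensity values on a linear scale, read by Agilent Feature Extraction 10.5.1.1 per the file headers and the submitters' processing notes. The mean and the median signal of each spot, its local background and its quality marks were deposited by the authors without further normalization. The deposited processed signals are intensity values after background subtraction and dye normalization by the same software, per the file headers. The LogRatio column is log10 of red over green as the scanner software computed it, per the file headers. The series matrix, as deposited by the authors, holds log2 values whose scale, centring and direction are not given in the sources used here. Set against the scanner values, all of its 4 columns equalled log2 of the green over the red processed signal for 100% of 41174 probes, within 0.001, which is treated over control with no centring. Its column medians were -0.26, 0.012, 0.11 and -0.058 for replicates 1 to 4.

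Each array had 45018 spots, of which 1639 were control spots. Background was corrected by normexp (offset 50) on the mean signal and the median local background, and the log2 ratio of green over red was normalized within each array by loess, with control spots at weight 0. Between 141 and 171 spots per array, marked as non-uniform or as population outliers, were left out, and no spot was saturated. Spots of a probe were averaged. Of 41174 probes, 27730 were well above background in the same channel on at least 3 of the 4 arrays and were kept. The brightest kept probe stood for each gene, which gave 18454 genes. Gene names came from the scanner files. They were updated through RefSeq accessions (25097 probes) or symbols and synonyms (7973 probes) from a GRCm38.p6 name table, and 8104 probes kept the name in the file. After the filter, 15608 of the 18454 genes had a matched name. Of 6608 genes with several kept probes, 558 had probes called in both directions. Probe coordinates are those of the files, in mm9.

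The log2 ratio of treated over control, with 1 value per array, was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), two-sided. P-values were adjusted over genes by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called higher or lower. Standard errors (SE) are those of this moderated fit. The ratio is relative to the central trend of each array, so a change shared by all genes is not measured. The number of arrays limits the precision, and the median SD of a gene's log2 ratio between arrays was 0.15. Gene levels per channel are means of log2 values after loess and Aquantile scaling. Samples of this group size were tested on simulated data: of 200 changed genes among 18454, the procedure recovered 28% of those changed 1.25-fold, 98% at 1.5-fold and 100% at 2-fold and at 4-fold. In that test 15 of 178 calls were false, and a true log2 shift of 2 in the raw intensities of 200 probes came back with a median of 2.06. The simulated noise was independent between genes and few genes changed, while 68.4% of genes were called in the real data. The p-value cut behind the adjusted p is therefore stricter in the simulation, and these shares do not give the recovery in the real data.

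Gene lists (24) were written before the data were examined, as were the test, the alternatives and the rule for the genes named. The lists were tested with camera of limma, which compares a list with all other genes, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists. They were also tested with the correlation estimated from the data and with fry. The rule took the 12 largest rises and 12 largest falls among called, name-matched genes with the same sign on all 4 arrays. It also took up to 4 members of each list that passed camera, by adjusted p in the direction of the list. A set of FGF, GDNF and spermatogonial genes was always given. Some genes that this rule takes are not reported here. Genes outside this rule are said to have been chosen after their values were seen. Of the set always given, Zbtb16 and Sohlh1 had no probe kept by the filter. The alternatives covered the normalization, the background correction, the filter on dim probes, the choice of probe, the spots left out, the variance model, the pairing within arrays and leaving out each replicate. A correction for probe base composition and the use of the second brightest probe were added after seeing the data. Spike-in spots lay close to background on all 4 arrays and were not used.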

Results

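Spermatogonial stem cells are the self-renewing germ cells of the testis. Here they had been derived from mice (C57/BL6 x DBA/2 F1) at day 5 and were grown in a serum-free medium with 40 ng/ml GDNF and 5 ng/ml FGF2. GDNF and FGF2 are growth factors that support their self-renewal in culture, and SU5402 blocks the tyrosine kinase of FGF receptors. The design asks which genes depend on FGF2 signalling. The 4 arrays each compared 1 culture without FGF2 and with SU5402 for 12 h with 1 culture in normal medium. The labels give the 12 h for the treated cells only, and whether feeder cells were present is not given in the sources used here. Between 26613 and 28496 of 41174 probes were well above background in the treated channel, and between 25533 and 27891 in the control channel. Ratios of different arrays correlated across genes with a Pearson r between 0.907 and 0.948, where genes are not independent replicates. As a check for an array deposited more than once, over 205 probes printed 10 times the SD of the difference between arrays was at least 0.21, against at most 0.026 expected from the repeat spots. All 4 arrays were therefore counted, and this check says nothing on how separate the cultures were.

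Ogn and Aspn were among the 12 genes with the largest rises after FGF2 withdrawal with SU5402, out of the genes with a matched name. These genes, which encode small proteoglycans of connective tissue, were 21.9-fold and 20.3-fold higher (log2 4.45, SE 0.071, and log2 4.35, SE 0.076, n = 4). Chl1 and Jam2, which encode cell adhesion proteins, had log2 ratios of 3.76 and 3.49, and Itgbl1, an integrin-like gene, of 3.71. Mybpc3, a myosin-binding protein of heart muscle, and Smpx, a small muscle protein, had log2 ratios of 3.66 and 3.44. Aard, known from Sertoli cells, was higher by 3.48, and Mro, a gene of the developing gonad, by 3.74. The remaining genes among the 12 largest rises were Misp3 (log2 3.83), Clca3a1, a chloride channel regulator (log2 3.66), and Fgl2, a fibrinogen-like protein (log2 3.49). The control signal of Fgl2 was well above background on only 2 of the 4 arrays. The order rests on the processing: with the scanner LogRatio Fgl2 was at 4.61, Aspn at 4.50 and Ogn at 4.37. The second brightest probes of Mro and Jam2 gave 2.08 and 2.18. The probe of Ogn lies on chromosome 13 at 49719549 to 49719608 and that of Aspn at 49662479 to 49662538 of the same chromosome (mm9).

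The 12 name-matched genes with the largest falls included Saa3, S100a8 and several chemokine genes. Saa3 and Saa1, which encode serum amyloid A proteins, were lower by log2 ratios of -4.85 (SE 0.11) and -3.62 (SE 0.10), and Saa3 was 28.9-fold lower. S100a8, a subunit of calprotectin in neutrophils and monocytes, had a log2 ratio of -4.47 (SE 0.13). The chemokine genes Ccl3, Ccl4, Ccl6 and Cxcl3 had log2 ratios of -3.36, -3.19, -2.98 and -2.92. Marco, a scavenger receptor of macrophages, fell by 3.21 on the log2 scale. Acod1, the itaconate-producing enzyme of activated macrophages, fell by 3.48. Stfa3, a cysteine protease inhibitor, had a log2 ratio of -4.03, Serpinb2, an inhibitor of plasminogen activators, of -3.59, and Fpr1, the formyl peptide receptor of phagocytes, of -2.94. All 24 of these rises and falls had the same sign on all 4 arrays, with limma adjusted p-values of at most 7.17e-08. In the treated channel, S100a8 was well above background on 2 of the 4 arrays, Cxcl3 on 1, and Stfa3, Acod1 and Fpr1 on 3, so their folds rest partly on signals near background. With the scanner LogRatio the order turned, with S100a8 at -5.96, Stfa3 at -5.24 and Saa3 at -5.18, and Cxcl3 was at -4.64. The probe of Saa3 lies on chromosome 7 at 53968031 to 53968090 and that of S100a8 on chromosome 3 at 90473778 to 90473837 (mm9).

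**Figure D1:**
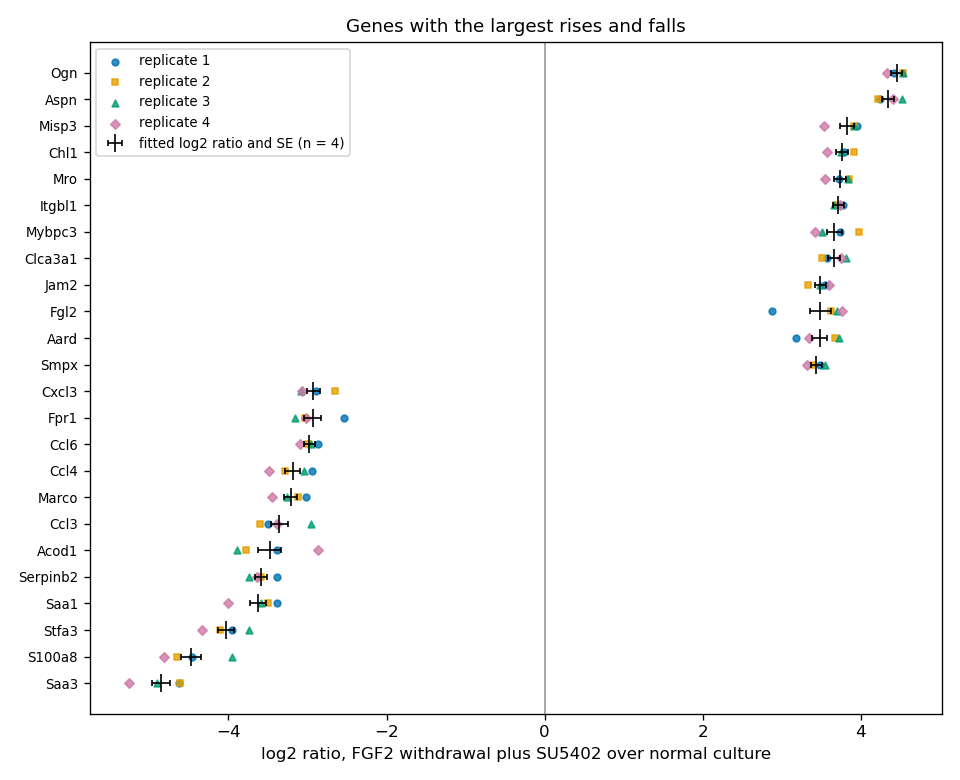
Log2 ratios (x axis) of the 12 name-matched genes with the largest rises and the 12 with the largest falls (y axis). Each gene has 1 point per array and a bar for the fitted value and its SE (n = 4). Ogn is at 4.45 and Saa3 at -4.85, and the points of each gene lie on 1 side of 0.

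Across all 18454 genes tested, limma called 6923 higher and 5708 lower at an adjusted p under 0.05, which together are 68.4% of the genes. At least 2-fold changes were mostly rises, with 2151 genes higher and 306 lower. The same sign on all 4 arrays was seen in 13566 genes (73.5%), where independent random signs give 12.5%. Dyes were not swapped, so a gene-specific dye effect could add both to this share and to the calls. Higher genes made up 54.8% of those called. This split depends on the processing. With the scanner software's own LogRatio 5598 genes were higher and 7855 lower (41.6% higher), and 981 instead of 306 were at least 2-fold lower. That LogRatio moved the median over all genes by -0.15. Centring alone did not undo the change: with median-centred processed signals 47.1% of called genes were higher and 818 were at least 2-fold lower. Median centring in place of loess gave 388 at least 2-fold lower.

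Genes of connective tissue and of contractile cells rose as groups. Of 32 genes of fibroblasts and feeder cells, 30 were higher and 1 was lower, with a median log2 ratio of 1.40 (camera adjusted p = 2.2e-09, and adjusted p = 0.15 with an estimated correlation). They included Fbn1, the main protein of microfibrils (log2 2.49), Timp3, an inhibitor of matrix proteases (2.42), Lum, a matrix proteoglycan (1.90), and Acta2, smooth muscle actin (1.99). Of 19 genes of the cytoskeleton and of serum response factor, 18 were higher and 0 lower, with a median of 1.68 (camera adjusted p = 4.78e-07, and adjusted p = 0.167 with an estimated correlation). Among these, the myosin light chain Myl9 had a log2 ratio of 2.54, calponin Cnn1 of 2.09 and Ankrd1 of 1.84. The second brightest probe of Acta2 gave 1.01. Of the fibroblast list, 5 genes are also in another list.

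Genes of the somatic cells of the testis were higher as well. Of 20 genes of Sertoli cells, the nurse cells of the seminiferous tubule, 18 were higher and 1 was lower, with a median log2 ratio of 1.58 (camera adjusted p = 9.71e-07, and adjusted p = 0.14 with an estimated correlation). Cldn11, a tight junction protein of these cells, was 10.7-fold higher (log2 3.42, SE 0.077), and the signal gene Dhh, the cystatin Cst12 and the transcription factor Sox9 had log2 ratios of 3.32, 3.17 and 2.53. The member that fell was Trf, transferrin, at -0.69, and Rhox5 was at -0.094 and passed no threshold (limma adjusted p = 0.33); both were chosen after their values were seen. Of 14 genes of Leydig and peritubular cells, which make steroids and surround the tubule, 13 were higher and 1 was lower, with a median of 1.56 (camera adjusted p = 1.94e-05, and adjusted p = 0.167 with an estimated correlation). Hsd3b1, a steroid-synthesis enzyme, had a log2 ratio of 3.16, the transcription factor Tcf21 of 2.93, smooth muscle myosin Myh11 of 2.36 and the growth factor gene Igf1 of 2.29. The second brightest probe of Igf1 gave 1.41.

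Most markers of blood and endothelial cells were lower, and 3 endothelial genes were higher. Of the 18 genes, 3 were higher and 14 lower, with a median log2 ratio of -0.42 (camera adjusted p = 0.00128, and adjusted p = 0.25 with an estimated correlation). The macrophage surface gene Adgre1 was 4.61-fold lower (log2 -2.21, SE 0.067). Cd14, a receptor for bacterial lipopolysaccharide, had a log2 ratio of -1.33, Fcer1g, an Fc receptor subunit, of -1.23, and the lysozyme gene Lyz2 of -1.15. The endothelial genes went both ways, with Cdh5 (1.20), Emcn (0.58) and Cd34 (0.43) higher and Kdr (-0.89), Vwf (-0.34), Esam (-0.30), Pecam1 (-0.29) and Flt1 (-0.27) lower, each called by limma. The leukocyte markers of the list, 8 in number, were all lower with a median of -1.03. These genes and this split were chosen after their values were seen. On second brightest probes the list, with only its members that have one, had a median of -0.027 (camera adjusted p = 0.305).

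Retinoic acid genes and genes of the TGF-beta family rose together with the somatic cell markers. Of 20 genes of retinoic acid metabolism and response, 16 were higher and 3 lower, with a median log2 ratio of 0.72 (camera adjusted p = 0.00128, and adjusted p = 0.186 with an estimated correlation). The retinaldehyde dehydrogenase Aldh1a1 had a log2 ratio of 2.97, the transglutaminase Tgm2 of 2.67, and the binding protein Crabp2 of 1.97. Stra8, which germ cells switch on in response to retinoic acid, was higher by 0.52 (SE 0.087, limma adjusted p = 0.000544), a call that ended with median centring in place of loess (0.31, limma adjusted p = 0.0759). Of 31 genes of BMP, TGF-beta and ID signalling, 22 were higher and 5 lower, with a median of 0.58 (camera adjusted p = 0.00513, and adjusted p = 0.156 with an estimated correlation). The ligand genes Tgfb3 and Tgfb2 had log2 ratios of 2.98 and 2.74, the inhibin subunit Inhbb of 2.21 and the secreted Tgfbi of 1.81. The second brightest probe of Inhbb gave 1.01. On second brightest probes both lists lost their calls, with medians of 1.02 for retinoic acid and 0.31 for BMP and TGF-beta (camera adjusted p = 0.291 and 0.707).

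Genes of cell division fell by small amounts on all 4 arrays, on which the Sertoli and fibroblast lists rose with medians of 1.58 and 1.40. Of 40 genes of G1/S and DNA replication, 29 were lower and 1 was higher, with a median log2 ratio of -0.50 (camera adjusted p = 9.71e-07, and adjusted p = 0.14 with an estimated correlation). The replicative helicase subunit Mcm5 had a log2 ratio of -1.10, the transcription factor E2f8 of -0.99, and thymidine kinase Tk1 and cyclin Ccne1 of -0.75 and -0.74. Of 35 genes of G2/M and mitosis, 28 were lower and 0 higher, with a median of -0.34 (camera adjusted p = 2.34e-06, and adjusted p = 0.167 with an estimated correlation). These included the cyclin Ccnf (-0.99), separase Espl1 (-0.81), the phosphatase Cdc25b (-0.77) and the centromere protein gene Cenpf (-0.70). The second brightest probe of Cenpf gave -0.22 (limma adjusted p = 0.0697). Of 34 genes of ribosome biogenesis and MYC targets, 19 were lower and 2 higher, with a median of -0.25 (camera adjusted p = 0.000346, and adjusted p = 0.15 with an estimated correlation). Rrp9, which acts in ribosomal RNA processing, had a log2 ratio of -1.16, the RNA polymerase I subunit Polr1b of -1.15, fibrillarin Fbl of -0.88 and the pyrimidine-synthesis enzyme Cad of -0.79. Fbl was at -0.57 with median-centred processed signals and at -1.41 with median centring in place of loess. On second brightest probes the G1/S list (median -0.30, camera adjusted p = 0.104) and the ribosome biogenesis list (median -0.065, camera adjusted p = 0.291) lost their calls.

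Inhibitors of the cell cycle and genes of p53, FOXO and metabolic responses were higher, together with the Sertoli and fibroblast lists (medians 1.58 and 1.40). Of 34 genes of p53, CDK inhibitors and apoptosis, 29 were higher and 3 lower, with a median log2 ratio of 0.73 (camera adjusted p = 3.06e-05, and adjusted p = 0.14 with an estimated correlation). The stress-response genes Gadd45b and Gadd45g had log2 ratios of 1.94 and 1.66, and the p53 targets Perp and Zmat3 of 1.71 and 1.62. The CDK inhibitor genes Cdkn1a and Cdkn1b were higher by 0.76 (SE 0.082) and 0.58 (SE 0.090), with limma adjusted p-values of 3.33e-05 and 0.000348. Of 27 FOXO targets, 17 were higher and 2 lower, with a median of 0.58 (camera adjusted p = 0.00409, and adjusted p = 0.206 with an estimated correlation). Pdk4, a kinase that limits pyruvate oxidation, had a log2 ratio of 2.41, Rbl2, a retinoblastoma-family gene, of 1.70, Sesn3 of 1.68 and Pik3ip1, an inhibitor of PI3 kinase, of 1.55. The second brightest probe of Sesn3 gave 0.065 (limma adjusted p = 0.547), that of Rbl2 0.87 and that of Pik3ip1 0.61. Of 34 genes of glycolysis and hypoxia, 24 were higher and 2 lower (3 lower adjusted over the list alone), with a median of 0.81 (camera adjusted p = 0.000208, and adjusted p = 0.167 with an estimated correlation). Pdk1 and Pfkfb3, regulators of glucose use, had log2 ratios of 1.55 and 1.26, and P4ha2 and Ero1a, which act in protein maturation, of 1.33 and 1.05. The second brightest probes of Pfkfb3 and Ero1a gave 0.65 and 0.54. Of 33 genes of cholesterol synthesis, 24 were higher and 2 lower, with a median of 0.42 (camera adjusted p = 0.0012, and adjusted p = 0.167 with an estimated correlation). The sterol enzymes Tm7sf2, Ebp and Pmvk had log2 ratios of 2.55, 1.98 and 1.52. On second brightest probes the p53, FOXO and cholesterol lists lost their calls, with medians of 0.26, 0.28 and 0.18 (camera adjusted p = 0.31, 0.291 and 0.296).

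Genes of spermatogonial self-renewal fell, while the Sertoli and fibroblast lists rose with medians of 1.58 and 1.40. Of 17 genes known to respond to GDNF, 13 were lower and 0 higher, with a median log2 ratio of -0.35 (camera adjusted p = 0.000464, and adjusted p = 0.156 with an estimated correlation). T (brachyury) was 3.03-fold lower (log2 -1.60, SE 0.11, limma adjusted p = 1.23e-06), and its probe lies on chromosome 17 at 8634870 to 8634929 (mm9). The transcription factor genes Eomes, Lhx1 and Pou3f1 had log2 ratios of -0.99, -0.96 and -0.79. Mycn was at -0.67, and Cxcr4, a chemokine receptor, at -0.53. Of 32 genes of undifferentiated spermatogonia, 17 were lower and 5 higher (19 lower adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.00409, and adjusted p = 0.167 with an estimated correlation). Among them, the RNA-binding protein genes Lin28b and Dnd1 had log2 ratios of -0.93 and -0.86, Pax7 of -0.85 and Taf4b of -0.71. The GDNF receptor kinase Ret was at -0.61 (SE 0.077), Sall4 at -0.44 (SE 0.12) and Foxo1 at -0.35 (SE 0.075), each called lower by limma. Second brightest probes gave smaller falls for Lhx1 (-0.63), Lin28b (-0.24, limma adjusted p = 0.048), Taf4b (-0.27), Sall4 (-0.21) and Foxo1 (-0.32). They gave larger falls for Mycn (-0.90) and Cxcr4 (-0.77). Pou3f1 was at -0.39 with the base composition trend removed. Larger falls came with the scanner LogRatio for Pax7 (-1.44) and Ret (-1.13) and with median centring in place of loess for Foxo1 (-0.60). Of 33 genes of differentiating spermatogonia and meiosis, 16 were lower and 7 higher (17 lower adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.033, and adjusted p = 0.167 with an estimated correlation). Kit, the receptor kinase of differentiating spermatogonia, had a log2 ratio of -0.69, the meiosis genes Tex15, Syce1 and Smc1b of -0.59, -0.58 and -0.47, and the DNA methyltransferase Dnmt3b of -0.56. Smc1b was at -0.72 with median centring in place of loess. The call of this last list ended with median-centred processed signals (median -0.33, camera adjusted p = 0.0642). On second brightest probes these 3 lists lost their calls, with medians of -0.20, -0.26 and -0.24 (camera adjusted p = 0.106, 0.0887 and 0.104). These medians are over the members with a second kept probe, which T, Eomes and Pou3f1 lack.

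Targets of the ERK pathway, the main route of FGF signals, did not move as a group. Of 38 such genes, 11 were higher and 11 lower, and the median log2 ratio of 0.057 (mean 0.091) lay on the other side of 0 from the camera test, which gave an adjusted p of 0.734 in the lower direction. Median values went from -0.098 to 0.085 across the alternatives. The phosphatase gene Dusp6 was at -0.011 (SE 0.072), Fos at 0.083 (SE 0.084), Ccnd1 at 0.082 (SE 0.071) and Myc at 0.18 (SE 0.099). Limma called none of these 4 here or with any alternative that gives 1 value per gene. Across those alternatives Dusp6 went from -0.34 to 0.026, Fos from -0.092 to 0.15, Ccnd1 from -0.078 to 0.11 and Myc from -0.069 to 0.26. With all kept probes tested singly, the dimmest of 3 Myc probes was called lower (-0.47, limma adjusted p = 0.00161). The brighter Myc probes, at 0.18 and 0.085, were not called. Of the genes that passed, Spry2, a feedback inhibitor, was at 0.46 (SE 0.11), Egr1 at 0.20 (SE 0.069) and Etv4 at -0.38 (SE 0.097). The call of Spry2 ended with the scanner LogRatio and the series matrix (0.28 each, limma adjusted p = 0.0621 and 0.0623) and that of Etv4 with median centring in place of loess (-0.33, limma adjusted p = 0.0644) or with the base composition trend removed (-0.22, limma adjusted p = 0.0753), while the scanner LogRatio gave -0.58 for Etv4. The second brightest probe of Spry2 gave 0.21. Etv5, a transcription factor required for stem cell maintenance, was at 0.056 (SE 0.10, limma adjusted p = 0.634) on its brightest probe and at -0.57 (limma adjusted p = 0.000451) on its second probe. The mean over the probes of Etv5 was called lower (-0.26, limma adjusted p = 0.0143), and no other alternative gave it a call. Spry4 was at 0.63 (SE 0.28, limma adjusted p = 0.07) on its brightest probe, with values from -0.29 to 1.83 between arrays, and at -0.47 (limma adjusted p = 0.00046) on its second. The brightest probe of Spry4 was called higher without replicate 1 (0.93, limma adjusted p = 0.0118), with median-centred processed signals (0.50, limma adjusted p = 0.00174) and with median centring in place of loess (0.72, limma adjusted p = 0.0202). It was at 0.22 without replicate 3 and at 0.059 with the base composition trend removed, and the mean over the probes of Spry4 was 0.078, none of them called. The call of Egr1 ended without replicate 2, 3 or 4, at limma adjusted p-values of 0.104, 0.0723 and 0.0843. Egr1 was at 0.18 with the smaller offset (limma adjusted p = 0.0565), at 0.14 with processed signals, at 0.091 with the scanner LogRatio and the series matrix, at 0.0017 with median centring in place of loess and at 0.031 with the base composition trend removed, and limma did not call it there.

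FGF receptors and ligands moved in both directions. Of 23 such genes, 13 were higher and 8 lower, and the median log2 ratio of 0.35 did not pass camera (adjusted p = 0.271). Fgfr2 was 3.01-fold higher (log2 1.59, SE 0.089, limma adjusted p = 3.89e-07), and its second probe gave 0.42. Fgfr3 was at -0.62 (SE 0.078), Fgfr4 at 0.35 (SE 0.071) and Fgf2 at 0.65 (SE 0.067), with Fgf2 well above background on only 1 of the 4 arrays in the control channel. Fgf2 was at 1.24 with the scanner LogRatio. The call of Fgfr4 ended with the scanner LogRatio and the series matrix (0.19 each, limma adjusted p = 0.0691 in both) and with processed signals (0.23, limma adjusted p = 0.162). Its mean over probes was 0.20, and with the base composition trend removed it was at 0.63. Fgfr1 was at -0.27 (SE 0.11) with a limma adjusted p of 0.0488, a call that ended without replicate 1, 3 or 4 (limma adjusted p = 0.101, 0.212 and 0.0802), with a value of -0.14 without replicate 3. The call of Fgfr1 also ended with median centring in place of loess, scaling between arrays and no filter on dim probes (limma adjusted p = 0.313, 0.0553 and 0.0683). Its mean over 4 probes was -0.017 (limma adjusted p = 0.867), and its value with the base composition trend removed was -0.070 (limma adjusted p = 0.509), neither of them called. With all kept probes tested singly, its second brightest probe was called lower (-0.29, limma adjusted p = 0.042). The third was called higher (0.52, limma adjusted p = 0.00325), and the dimmest, at -0.035, was not called. Fgfr1 was called lower with the scanner LogRatio and the series matrix (-0.51 each, limma adjusted p = 0.00634 and 0.00641) and with processed signals (-0.46).

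**Figure D2:**
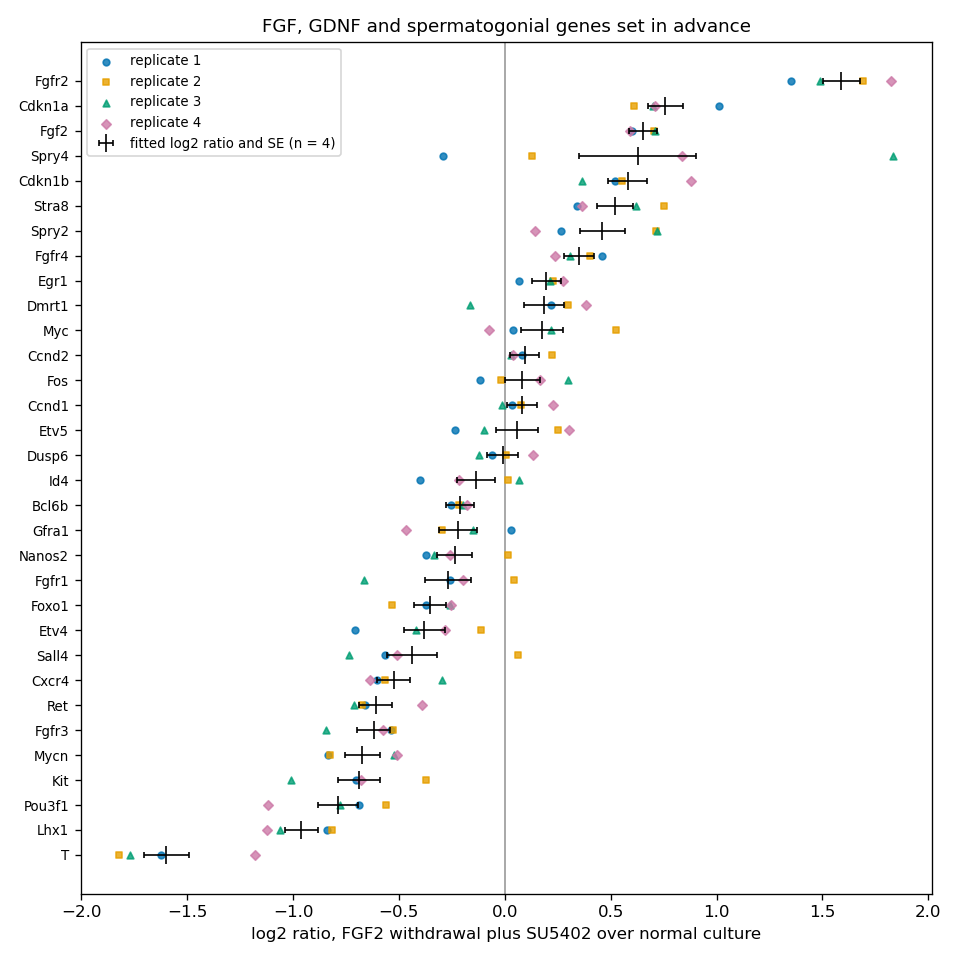
Log2 ratios (x axis) of the FGF, GDNF and spermatogonial genes set before the data were examined (y axis), with 1 point per array and a bar for the fitted value and its SE (n = 4). Fgfr2 is at 1.59 and T at -1.60, and the points of Spry4 spread from -0.29 to 1.83.

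Several other stem cell genes stayed near 0 or near the threshold, and their calls changed with the processing or with the replicate left out. Bcl6b, a GDNF target, was at -0.21 (SE 0.065, limma adjusted p = 0.0165), and its call ended without replicate 1 or 2 (limma adjusted p = 0.0668 and 0.06). The call of Bcl6b also ended with median centring in place of loess (-0.21, limma adjusted p = 0.256) and with median-centred processed signals (-0.32, limma adjusted p = 0.0503), and was kept with the scanner LogRatio and the series matrix (-0.37 each). Nanos2 was at -0.24 (SE 0.082, limma adjusted p = 0.0275), a call that ended without replicate 1, 3 or 4 (limma adjusted p = 0.116, 0.0948 and 0.0676). The call of Nanos2 also ended with median centring in place of loess (-0.15, limma adjusted p = 0.377), with no replicate block (limma adjusted p = 0.0593) and with the base composition trend removed (-0.18, limma adjusted p = 0.0597). It was kept with the scanner LogRatio and the series matrix (-0.49 each) and with processed signals (-0.44). Id4 was at -0.13 (SE 0.090), Dmrt1 at 0.18 (SE 0.095) and the cyclin gene Ccnd2 at 0.094 (SE 0.069), and limma called none of them. Ccnd2 was called higher on its second probe (0.50, limma adjusted p = 0.00166), with the scanner LogRatio and the series matrix (0.32 each), with processed signals (0.37), as the mean over probes (0.22) and with the base composition trend removed (0.26). It was called lower with median centring in place of loess (-0.38, limma adjusted p = 0.0439). Id4 was called at -0.25 (limma adjusted p = 0.0236) with the base composition trend removed, and its values went from -0.35 to -0.045 across the alternatives, against -0.010 to 0.30 for Dmrt1. Without replicate 3, Dmrt1 was called at 0.30 (limma adjusted p = 0.0111) and the call of Sall4 ended at -0.34 (limma adjusted p = 0.0507). Gfra1, the GDNF co-receptor, was at -0.22 (SE 0.089, limma adjusted p = 0.0512) on its brightest probe. Limma called it lower on its second probe (-0.69, adjusted p = 0.000172), as the mean over probes (-0.45, adjusted p = 0.000186), with the scanner LogRatio and the series matrix (-0.42 each, adjusted p = 0.00517 and 0.00521) and with processed signals (-0.37, adjusted p = 0.0226). It was also called without replicate 1 (-0.30, limma adjusted p = 0.0209), and with no background correction, the smaller offset and robust eBayes (limma adjusted p = 0.0491, 0.0452 and 0.0492). Gfra1 stayed uncalled with the other alternatives. Among these were the fit without replicate 4 (-0.14, limma adjusted p = 0.197) and the base composition trend removed (-0.11, limma adjusted p = 0.283).

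Of the 24 lists, 17 passed camera, 10 of them higher and 7 lower, and the median of each of these 17 had the same sign on all 4 arrays. With an estimated correlation 0 lists passed, against 7 at an unadjusted p under 0.05 and 20 with fry. On the second brightest probe of each gene, where fewer genes were tested, 11 of the 17 no longer passed camera. Each list then held only its members with a second kept probe, so these medians are over other sets of genes. The Sertoli, Leydig and peritubular, fibroblast, cytoskeleton, glycolysis and G2/M lists still passed. For all lists but the 3 given with such a count above and the interferon list, the calls adjusted over the list alone had the same numbers as those adjusted over all genes.

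**Figure D3:**
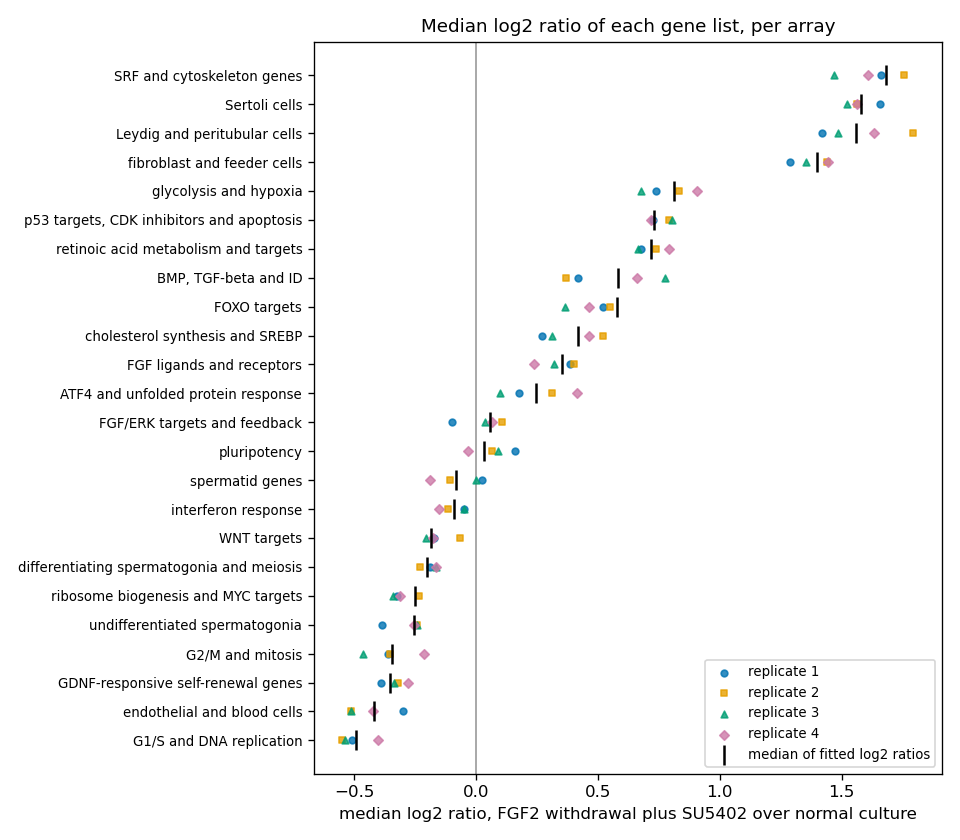
Median log2 ratio (x axis) of each of the 24 gene lists (y axis), with 1 point per array and a black bar for the median of the fitted values. The Sertoli, Leydig and peritubular, fibroblast and cytoskeleton lists lie above 1 on all 4 arrays, and G1/S is at -0.50.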

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

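The test for single samples that stand apart used a fixed rule. It was run on 151 items (the named genes, the list medians and the array quality values, each over 4 arrays), and a gap to the nearest array above the 95% critical value of Dixon, as a share of the whole range, picked out 8 of them, where chance alone gives about 7.55. Replicate 4 accounted for 4 of the 8. In replicate 4 the log2 ratio of Misp3 was 3.53, against 3.91 to 3.95 on the other arrays. The ratio of Cldn11, a tight junction gene of Sertoli cells, was 3.20 in replicate 4, against 3.47 to 3.51. The sterol enzyme gene Tm7sf2 was at 2.13 in replicate 4, against 2.65 to 2.74. The GDNF receptor kinase gene Ret was at -0.39 in replicate 4, against -0.71 to -0.66. Fgl2 was at 2.88 in replicate 1, against 3.62 to 3.76. In replicate 1 the median of the list of undifferentiated spermatogonia was -0.39, against -0.26 to -0.24. Smooth muscle myosin Myh11 was at 2.63 in replicate 2, against 2.23 to 2.30. Fgfr3 was at -0.84 in replicate 3, against -0.57 to -0.53. Each of these 8 items kept its sign on all 4 arrays.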

How the results depend on the processing

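The removal of a probe base composition trend and the use of the second brightest probe were added after seeing the data. The cause of a changed call was not tested for any alternative. Leaving out each replicate gave 6448 to 6751 genes higher, 4999 to 5392 lower, 2104 to 2220 at least 2-fold higher and 279 to 331 at least 2-fold lower. The count of genes at least 2-fold lower (306) became 981 with the LogRatio of the scanner software, 980 with the series matrix and 818 with median-centred processed signals. The median over all genes moved by -0.15 in the former pair. The series matrix gave 5593 genes higher and 7852 lower. Median centring without loess gave 3577 genes lower in place of 5708. Fitting the channels as separate samples with no replicate block gave 6681 higher and 5471 lower. Ccnd2 (0.094, uncalled) turned to -0.38 with median centring without loess, and Etv5 (0.056, uncalled) to -0.26 with the mean over its probes. With the second brightest probe, Etv5 was at -0.57 and Spry4 at -0.47. Of the 121 named genes, between 111 and 121 kept both sign and call with each alternative that gave a value for all of them. The 111 came with the scanner LogRatio and the series matrix, where 5 calls changed and 5 uncalled genes turned sign (Etv5, Fos, Ccnd1, Myc and Dmrt1). Of 47 with a second probe, 41 kept both.

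With an estimated correlation the medians are the same and the adjusted p alone changes. The 17 lists that passed camera then had adjusted p-values from 0.14 to 0.25, with medians of 1.40 (fibroblast), 1.58 (Sertoli), 1.56 (Leydig and peritubular), 1.68 (cytoskeleton), 0.73 (p53), 0.58 (FOXO, and BMP and TGF-beta), 0.42 (cholesterol), 0.81 (glycolysis), 0.72 (retinoic acid), -0.35 (GDNF-responsive), -0.25 (undifferentiated, and ribosome biogenesis), -0.20 (differentiating), -0.50 (G1/S), -0.34 (G2/M) and -0.42 (blood and endothelial). The estimate was below the preset 0.01 for the p53 (-0.0097), differentiating (-0.0082), BMP and TGF-beta (-0.0017) and ribosome biogenesis (0.0098) lists. A correlation above the preset was therefore not what ended the calls of these lists. The other lists that passed had estimates above 0.01, up to 0.24 for the cytoskeleton list. Using fry, 3 further lists passed: FGF ligands and receptors (0.35), ATF4 and unfolded protein response (0.24) and interferon response (-0.092). With the second brightest probe, where fewer genes were tested, 11 lists no longer passed camera: GDNF-responsive (-0.20), undifferentiated (-0.26), differentiating (-0.24), G1/S (-0.30), p53 (0.26), FOXO (0.28), cholesterol (0.18), ribosome biogenesis (-0.065), retinoic acid (1.02), BMP and TGF-beta (0.31) and blood and endothelial (-0.027). Differentiating spermatogonia lost its call with median-centred processed signals (-0.33). No sign of these 17 medians changed under any alternative. Slide and scan as a block were not run, because there was 1 of each. Signals near background limit the folds of S100a8, Cxcl3, Stfa3, Acod1, Fpr1, Fgl2 and Fgf2.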

Other observations

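All tests of explanations given here, apart from the other assignments of the treated label, were chosen after the result was seen. The genes singled out in this and the next paragraph were also chosen after their values were seen. Of 37 genes of the ATF4 and unfolded protein responses, 18 were higher and 9 lower (median 0.24, camera adjusted p = 0.225). Atf5 and Herpud1, a transcription factor and a gene of endoplasmic reticulum stress, had log2 ratios of 1.60 and 1.39. The amino acid transporter genes Slc7a5 and Slc3a2, whose products form 1 carrier, were at -1.10 and -0.64. Of 18 WNT targets, 4 were higher and 9 lower (median -0.19, mean 0.068, camera adjusted p = 0.271). Lgr5 and Axin2, both WNT-induced, were at 2.68 and 1.18, while Sp5 was at -0.85.

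Of 28 interferon response genes, 9 were higher and 13 lower (10 and 13 adjusted over the list alone), with a median of -0.092 and a camera adjusted p of 0.225. Ifit2 had a log2 ratio of 1.75 and Oas1a, which senses viral RNA, of -1.43. Among 16 pluripotency genes, 5 were higher and 3 lower, with a median of 0.034 and a camera adjusted p of 0.936. Pou5f1 was at 0.0095 (SE 0.12) and Sox2 at 0.51. Spermatid genes gave 3 higher and 2 lower of 15, with a median of -0.083, a mean of 0.021 and a camera adjusted p of 0.556. The retinoic acid-degrading enzyme gene Cyp26a1 was at -1.05 although its list rose.

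The joint rise of Sertoli, Leydig, peritubular and fibroblast genes was weighed against technical causes. Second probes that do not overlap the brightest one had a median log2 ratio of 1.38 over 23 members of these lists, and all 23 had the sign of the brightest probe, which argues against a dye effect of single probes as the whole cause. A lower share of germ cells with all other cell types unchanged would raise leukocyte markers too, but 8 such markers had a median of -1.03, against 1.58 for Sertoli genes. More RNA of somatic testis cells or fibroblasts and regulation within those cells by the treatment both stay open and were not tested, since cell shares were not measured. Whether such cells were in the cultures is not given in the sources used here. Which cells made this RNA is therefore not known. In the controls, 15 of 20 Sertoli genes were above background on all 4 control arrays.

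Leukocyte markers fell together with the genes that were at least 2-fold lower. Of 74 genes at least 2-fold lower with a second, non-overlapping probe, 95.9% were below 0 on that probe too. Over all 6358 genes with such a probe, 74.8% had the same sign on both. This argues against a dye effect of single probes as the whole cause. The falls were smaller on the second probe, with a median of -0.73 against -1.14 on the brightest. The 8 leukocyte markers, a subset of the blood and endothelial list, had unequal log2 ratios from -0.50 for Ptprc to -2.21 for Adgre1. Less macrophage RNA and lower expression per cell both stay open and were not tested. The blood and endothelial list had a median of -0.027 on second brightest probes, but over only its members that have one, endothelial genes included. The leukocyte markers Fcer1g and Lyz2 were at -1.17 and -1.06 on their second probes. Adgre1 and Cd14 had no second kept probe, and those of the other leukocyte markers were not examined singly.

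Self-renewal genes fell in cultures where somatic genes rose. Dilution of germ cell RNA by somatic RNA could lower all germ cell genes alike. The 14 self-renewal genes found in no other germ cell list had a median of -0.45, against -0.25 for 62 other germ cell genes (difference -0.20, two-sided permutation test over genes, p = 0.126). Dilution and a loss of the self-renewal program through FGF signalling cannot be told apart by this test, because the difference lies within what random draws of genes give. The germ cell genes did not fall alike. Quartiles were -0.79 and -0.21 in the GDNF-responsive list, -0.58 and 0.020 in the undifferentiated list and -0.41 and 0.18 in the differentiating list. This spread cannot decide on equal dilution, because members that other cells also express, and dye effects of single genes, can widen it. Which members other cells express was not tested. Dilution as the whole or a part of the cause stays open.

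The treated label can be assigned within the 4 arrays in 8 ways, which is too few for a share under 0.05. The real assignment gave 12631 called genes with limma and the highest other gave 0 (with 179 genes at an unadjusted p under 0.05), and only 1 of the 8 reached the real number. For genes changed at least 2-fold the values were 2457 and 0, and again 1 assignment reached the real number. For gene lists passing camera, the real assignment gave 17 and the highest other also 17, so that 2 of the 8 reached that number. The assignments that turned 1 array gave 14 to 17 lists, and those that turned 2 gave 0 or 1. With 1 array turned, the other arrays keep the real sign, so part of the shift of each list remains. Turned arrays also widen the spread of each changed gene between arrays, which lowers the calls of single genes. Neither the 17 lists nor the 0 gene calls are therefore a level that chance alone gives.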
